A study of Homo sapiens with 18 samples.

How the data were processed

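RNA levels were measured on 18 Affymetrix arrays, 1 per sample, in the human embryonic kidney cell line HEK293. The cells had been transfected with an expression vector for RHOXF1, for RHOXF2, or with a control vector. RNA was taken 24 h or 48 h later, which gives 6 groups of 3 arrays. The labels describe the arrays of a group as biological triplicates. They name Lipofectamine 2000 as the transfection reagent and OriGene as the source of the plasmids. The treatment text names a GFP vector, pCMV6-AC-GFP, beside the RHOX clones. Whether the RHOX plasmids also encode GFP is not stated. RNA with an integrity number above 7 was used.

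The values are log2 RMA expression values as deposited by the authors, from Affymetrix Expression Console 3.1 per the labels: background-corrected, quantile-normalized and summarised per transcript cluster. That they are on a log2 scale was checked on the values. These lay within the range of log2 intensities on every array, and the array medians over all transcript clusters ran from 6.68 to 6.82. The array descriptions name the Human Gene ST array, version 1.0, and the identifiers belong to it, while the series text names an exon array of the same generation. The genome build behind the annotation is not named, so no positions are given.

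The table holds 33297 transcript clusters. Of these, 21214 carried at least 1 gene symbol and were tested; 19460 carried exactly 1 symbol, 1754 several, and 12083 none. Among the named clusters, 703 had values identical to another named cluster on every array. Symbols came from the probe table supplied with the series and matched the reference gene table for 19429 Entrez identifiers. No filter on dim clusters was applied. No array was left out, and no pair of arrays held identical values.

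Each cluster was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings) with 1 mean per group, over all 18 arrays and 12 residual degrees of freedom. The moderated variance had 6.5 prior degrees of freedom and a prior standard deviation of 0.124. Tests were two-sided, and p values were adjusted over the 21214 clusters of each comparison by the Benjamini-Hochberg method at 0.05. The comparisons were each transfected gene against control at each time, RHOXF1 against RHOXF2 at each time, the difference of each effect between the times, and control arrays at 48 h against 24 h. Standard errors are limma's moderated ones, and SD is that of the 3 arrays of a group. The number of arrays limits the precision. A "gene" in the counts below is a transcript cluster with a symbol.

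Genes were named by a rule. RHOXF1 and RHOXF2 were always named. For each comparison with control, the rule took up to 10 rises and up to 10 falls that passed the test and whose 3 arrays all lay outside the control range. It was filled up to 5 in a direction by the smallest p, given as values that did not pass. From each gene list, up to 3 members with the smallest p and those that passed were added. The comparisons other than with control took up to 5 in each direction. For these, and for RHOXF2 against control at 48 h, every heat shock gene measured was added. A gene with several clusters was named by the brightest. Clusters that list several near-identical genes (RHOXF2 with RHOXF2B, HSPA1A with HSPA1B, HSPA7 with HSPA6) lie outside the rule on single symbols and are named as such.

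Of 22 gene lists, 21 were tested as sets with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 84 tests of the 4 comparisons with control. The list of transfected genes was not tested as a set. The lists covered the heat shock response, endoplasmic reticulum (ER) chaperones, ATF4 targets, interferon-stimulated genes, NF-kappa-B targets, immediate early genes, p53 targets, apoptosis regulators, oxidative stress genes with metallothioneins, hypoxia and glycolysis, cholesterol synthesis, G1/S genes, G2/M genes, replication-dependent histones, HOX genes, germ cell genes, Sertoli and Leydig cell genes, markers of other cell types, neuronal and neural crest genes expressed by HEK293, ribosomal protein genes and small noncoding RNAs. Each list was also tested with a correlation estimated from the data. Medians of lists were set beside 10000 random lists matched on mean level.

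Overlaps between comparisons that share control arrays were set beside 50 simulations of unchanged groups. Their correlations across genes leave out the clusters of the transfected genes, a choice made after a first look at the values, as was the comparison with separate control arrays. The group numbers were checked for pairing. Residuals of arrays with the same number correlated above 0.1 in 8 of 9 pairs at 24 h and in 2 of 9 at 48 h. Among arrays of the other groups, 8 of 9 arrays at 24 h correlated best with their own number, and 2 of 9 at 48 h. A replicate block was planned only as an alternative. The reported tests use no block and so leave out this pairing at 24 h.

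The fit was tested on simulated data in which known changes had been added. Changes of 1 on the log2 scale were recovered in 97% to 100% of cases and changes of 0.5 in 67.2% to 74.6%. Of the calls, 3.7% to 6.8% were false. The simulated arrays were drawn independently, and the many added changes gave 190 to 192 calls per comparison, which eases the adjusted threshold. These shares check the procedure and do not give the recovery or the false calls of the real comparisons.

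Alternatives were fixed before the data were examined, with the lists, the tests and the naming rule. They were a fit of only the groups compared, trend and robust variances (with statmod 1.5.0), clusters above the median level, all clusters named or not, arrays centred on their medians, quantile normalization repeated, a replicate block, array weights, an unadjusted threshold with a 2-fold change, an estimated correlation for the lists, and leaving out each array. Cyclic loess normalization was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.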

Results

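Expression was measured in HEK293 cells 24 h and 48 h after transfection with RHOXF1, RHOXF2 or a control vector, with 3 arrays in each of the 6 groups. RHOXF1 and RHOXF2 encode homeodomain proteins of the reproductive homeobox family, encoded on the X chromosome. The arrays were compared to find which transcripts differ when either gene is introduced. Between replicate arrays of a group, values correlated across clusters at 0.9925 to 0.9975. The first principal component held 34.1% of the variance and the second 13.4%. The first mainly separated the times: 24 h arrays lay between -17.2 and -8.7, and 48 h arrays between 9.4 and 26.3, except RHOXF2 replicate 3 at 48 h, at -4.5. Array numbers 1 to 9 are all 24 h and 16 to 24 all 48 h, so time and array batch cannot be told apart.

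**Figure D1:**
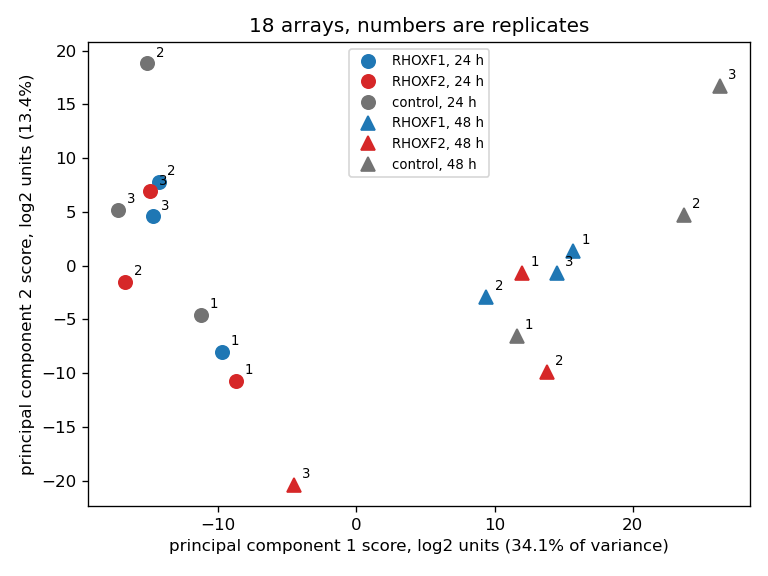
Each point is an array, placed by its scores on principal components 1 (34.1% of variance, x axis) and 2 (13.4%, y axis), with colour for the vector and symbol for the time. RHOXF2 replicate 3 at 48 h, at -4.5 on the first and -20.4 on the second component, stands apart from the other 48 h arrays.

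The transfected genes were present in the arrays that the labels name. RHOXF1 was 60.2-fold higher than control in RHOXF1-transfected cells at 24 h (log2 change 5.91 ± 0.34 SE, n = 3 against 3, limma adjusted p = 1.78e-08) and 70.7-fold higher at 48 h (6.14 ± 0.34, adjusted p = 9.06e-09). The cluster shared by RHOXF2 and its near-identical copy RHOXF2B was 64.6-fold higher in RHOXF2-transfected cells at 24 h (6.01 ± 0.23, adjusted p = 4.96e-12) and 78.6-fold higher at 48 h (6.30 ± 0.23, adjusted p = 2.17e-12). The RHOXF1 cluster lay at or above percentile 97.7 of the RHOXF1 arrays and that of RHOXF2 at or above percentile 99.1 of the RHOXF2 arrays, where signal can be compressed, so these folds are array values and not transcript numbers. The RHOXF2 cluster appears on the array as a pair of identical clusters, and the array does not separate RHOXF2 from RHOXF2B. In RHOXF1-transfected cells the RHOXF2 cluster differed from control by -0.28 at 24 h (adjusted p = 0.961) and by -0.18 at 48 h (adjusted p = 0.905). In RHOXF2-transfected cells RHOXF1 read 1.14 ± 0.34 above control at 24 h (adjusted p = 0.449). At 48 h RHOXF1 rose by 1.84 ± 0.34 (adjusted p = 0.0462), with levels of 7.75, 7.03 and 9.12 against 5.67, 6.20 and 6.51 in control. That call was lost without RHOXF2 replicate 3 (1.26, adjusted p = 0.0998), and without control replicate 1 (1.61, adjusted p = 0.0551), 2 (1.88, adjusted p = 0.148) or 3 (2.03, adjusted p = 0.0565). Over the other alternatives its adjusted p ran from 0.0122 to 0.648.

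**Figure D2:**
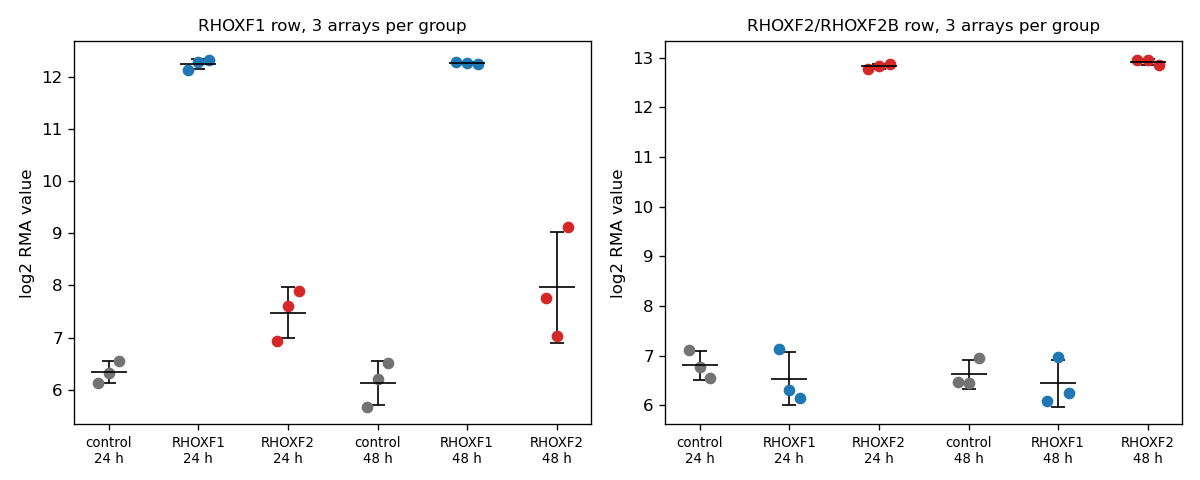
Log2 RMA level (y axis) of RHOXF1 and of the RHOXF2/RHOXF2B cluster in each of the 6 groups (x axis); points are arrays and bars are the mean ± SD of 3. Each gene lies above 12 in its own transfected arrays, and RHOXF1 in the RHOXF2 arrays runs from 6.94 to 9.12.

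RHOXF1 at 24 h: apart from RHOXF1 itself, no gene changed past the threshold. The genes with the smallest p that read higher were SNAI1, a transcription factor of epithelial-mesenchymal transition (0.53 ± 0.13), SLITRK3 (0.51 ± 0.14), NDUFV1-DT (0.37 ± 0.10) and CAMK2N1, an inhibitor of calcium/calmodulin-dependent kinase II (0.36 ± 0.10). Among those that read lower were FFAR3, a short-chain fatty acid receptor (-0.44 ± 0.09), OR52I1 (-0.41 ± 0.10) and GMFG (-0.34 ± 0.08). All had an adjusted p of 0.961. By limma, 1 gene was called, and 1009 had an unadjusted p under 0.05 (343 higher and 666 lower), where 1061 are expected by chance.

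Among the gene lists at 24 h with RHOXF1, the immediate early genes, which respond within minutes to growth signals, had 15 of 19 members higher (median 0.048, camera adjusted p = 0.00141; adjusted p = 0.831 with an estimated correlation). Adjusted over the list alone, 2 members were called; the smallest p belonged to NR4A2 (0.43 ± 0.13) and CCN2 (0.30 ± 0.09), and EGR1 read 0.34 ± 0.13. Heat shock genes had 14 of 17 members higher (median 0.075, adjusted p = 0.0177; adjusted p = 0.831 with an estimated correlation), and 0 were called over the list alone, with DNAJB1, a co-chaperone of HSP70, at 0.64 ± 0.22. Germ cell genes had 31 of 44 members lower (median -0.044, adjusted p = 0.0181; adjusted p = 0.778 with an estimated correlation), among them PIWIL1 (-0.23) and the protamine gene PRM2 (-0.22). Small noncoding RNAs had 139 of 217 members lower (median -0.062, adjusted p = 0.0159; adjusted p = 0.831 with an estimated correlation). Dim genes in general read lower in the RHOXF1 arrays at this time: in the dimmest of 5 bins by mean level the median was -0.046 with 66.8% of genes lower, and in the brightest 0.037 with 32.3% lower. Among random lists of the same levels the medians of immediate early genes (percentile 83.4) and heat shock genes (97.1) lay inside the central 95%, as did that of germ cell genes (32.1). The heat shock call was lost without control replicate 1 (adjusted p = 0.156) or 2 (0.0833), or RHOXF1 replicate 2 (0.0875) or 3 (0.0542), and the immediate early call without control replicate 2 (0.0728). The germ cell call was lost without control replicate 1 (0.141) or 2 (0.0767), or RHOXF1 replicate 1 (0.0692), and that of small noncoding RNAs without control replicate 2 (0.803) or 3 (0.391), or RHOXF1 replicate 1 (0.545). Medians that stayed called still moved: without control replicate 1 to 0.153 for immediate early genes and -0.159 for small noncoding RNAs, without RHOXF1 replicate 2 to 0.019 for immediate early genes, without RHOXF1 replicate 1 to 0.120 for heat shock genes, and without control replicate 3 to -0.083 for germ cell genes. With clusters above the median level the germ cell median turned to 0.018 (adjusted p = 0.389), and its call was also lost with repeated quantile normalization (-0.039, adjusted p = 0.182) and cyclic loess (-0.027, adjusted p = 0.271). Heat shock genes lost their call above the median level (adjusted p = 0.0708) and with cyclic loess (median 0.046, adjusted p = 0.1), and immediate early genes above the median level (adjusted p = 0.204). Over the alternatives the adjusted p ran from 0.0167 to 0.778 for germ cell genes, from 0.0105 to 0.831 for heat shock genes and from 6.35e-05 to 0.831 for immediate early genes.

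RHOXF2 at 24 h: apart from the RHOXF2 clusters, no gene changed past the threshold. Those nearest to it were KRT23, a keratin (-0.50 ± 0.10), DIP2C-AS1 (-0.45 ± 0.09), USH1G (-0.44 ± 0.09), CIROZ (-0.39 ± 0.08) and NOBOX, an oocyte homeobox gene (-0.36 ± 0.08), with SUMO1P3 (0.63 ± 0.15) and MIR217 (0.32 ± 0.08) on the higher side. These 7 had an adjusted p of 0.333. By limma, 2 clusters were called, and 1694 had an unadjusted p under 0.05, 364 higher and 1330 lower. Without control replicate 3 the count was 7.

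Heat shock genes were the list with the smallest p in RHOXF2-transfected cells at 24 h: 15 of 17 members were higher (median 0.205, adjusted p = 1.43e-06; adjusted p = 0.361 with an estimated correlation), and 4 were called when adjusted over the list alone. Without control replicate 1 the median was 0.10, with the list still called. BAG3, a co-chaperone induced by protein stress, read 0.41 ± 0.11 (adjusted p = 0.394 over all genes), DNAJB1 0.69 ± 0.22 (adjusted p = 0.449) and HSPA6, a strictly inducible HSP70 gene, 0.88 (adjusted p = 0.477). ATF4 targets, which answer amino acid and translation stress, had 19 of 20 members higher (median 0.132, adjusted p = 0.00647; adjusted p = 0.831 with an estimated correlation), with SESN2 at 0.30. G1/S genes had 21 of 24 higher (median 0.072, adjusted p = 0.0105; adjusted p = 0.831 with an estimated correlation), with the replication licensing factor CDT1 at 0.41. Replication-dependent histones had 17 of 19 higher (median 0.109, adjusted p = 0.028; adjusted p = 0.831 with an estimated correlation). Germ cell genes had 31 of 44 lower (median -0.071, adjusted p = 0.0271; adjusted p = 0.813 with an estimated correlation), with the transition protein gene TNP1 at -0.40. Markers of other cell types had 20 of 23 lower (median -0.095, adjusted p = 0.0145; adjusted p = 0.831 with an estimated correlation), with CD14 at -0.46. Dim genes again read lower: the median was -0.063 in the dimmest of the 5 bins, with 71% lower, and 0.036 in the brightest, with 31.7% lower. The G1/S median lay at percentile 96.3 of random lists of the same levels, inside the central 95%, as did germ cell genes (15.9) and markers of other cell types (12.1). The call was lost for ATF4 targets without control replicate 2 (adjusted p = 0.0833) or 3 (0.0538), for G1/S genes without control replicate 2 (0.136) or RHOXF2 replicate 1 (0.0526) or 3 (0.112), and for histones without control replicate 1 (0.135) or 2 (0.0851) or RHOXF2 replicate 1 (0.0552) or 2 (0.0999). It was lost for germ cell genes without control replicate 1 (0.135) or 2 (0.0833) or RHOXF2 replicate 3 (0.256), and for markers of other cell types without control replicate 1 (0.156) or RHOXF2 replicate 3 (0.266). Still called, the median was 0.246 for ATF4 targets without control replicate 1 and 0.166 for histones without control replicate 3. With repeated quantile normalization and with cyclic loess only 14 of 24 G1/S genes were higher, with medians of 0.030 (adjusted p = 0.249) and 0.031 (adjusted p = 0.425). Germ cell genes went to -0.031 (adjusted p = 0.233) and -0.019 (adjusted p = 0.316; 18 of 44 higher), and markers of other cell types to -0.075 (adjusted p = 0.0924) and -0.058 (adjusted p = 0.177), so these calls were lost under both. Histones were lost with cyclic loess (0.070, adjusted p = 0.0613), and above the median level ATF4 targets (adjusted p = 0.165), G1/S genes (adjusted p = 0.204) and histones (adjusted p = 0.554). Over the alternatives the adjusted p ran from 0.00401 to 0.831 for G1/S genes, from 0.0034 to 0.813 for germ cell genes, from 0.00621 to 0.831 for markers of other cell types, from 0.00439 to 0.831 for histones and from 6.04e-06 to 0.831 for ATF4 targets.

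RHOXF1 at 48 h: ADAM20P1, a pseudogene of the ADAM protease family, fell by 1.08 on the log2 scale (SE 0.14, adjusted p = 0.00375; 4.14 ± 0.22 SD against 5.22 ± 0.32 SD, n = 3), and besides RHOXF1 it was the only gene called. Its control level at 48 h was itself high: ADAM20P1 averaged 4.25 in control cells at 24 h. The cluster is dim: in those controls and in the RHOXF1 arrays at 48 h it lay below the lower quartile of all clusters (4.86 to 5.02 over the arrays). Genes next to the threshold were the tight junction gene CLDN1 (0.66 ± 0.11, adjusted p = 0.0727), DNAJB1 (1.12 ± 0.22, adjusted p = 0.278), SNORD117 (-0.80 ± 0.15, adjusted p = 0.278), DTX2 (0.48 ± 0.10, adjusted p = 0.368) and the orphan receptor GPR63 (-0.40 ± 0.08, adjusted p = 0.368). limma called 2 genes, and 1531 had an unadjusted p under 0.05, 869 higher and 662 lower. The ADAM20P1 call was lost without RHOXF1 replicate 2 (adjusted p = 0.0516) or 3 (0.0597), with 1 gene called in each case, and without RHOXF1 replicate 1 the count was 4. It was also lost with only the RHOXF1 and control arrays of 48 h fitted (-1.08, adjusted p = 0.439), and over the alternatives its adjusted p ran from 0.00185 to 0.439.

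In the RHOXF1 arrays at 48 h all 17 heat shock genes measured were higher than control, 16 after repeated quantile normalization (median 0.200, adjusted p = 6.17e-07; adjusted p = 0.361 with an estimated correlation), and 3 were called when adjusted over the list alone. Their mean was 0.27 above the control arrays of 48 h and 0.03 above those of 24 h, since the control mean itself was 0.24 lower at 48 h. The smallest p belonged to DNAJB1, HSPA2 (0.43 ± 0.13) and the constitutive HSP70 gene HSPA8 (0.23 ± 0.07). Small noncoding RNAs had 152 of 217 members lower (median -0.100, adjusted p = 1.14e-05; adjusted p = 0.831 with an estimated correlation), with SNORA38 at -0.63 and SNORD77 at -0.60; this call was lost without RHOXF1 replicate 1 (adjusted p = 0.0864), and the median was -0.184 without replicate 2. Immediate early genes had 11 of 19 members higher (median 0.007, adjusted p = 0.543), with 3 called over the list alone; FOSB read 0.63, EGR1 0.44 and CCN2 0.32.

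RHOXF2 at 48 h gave the largest set of changes among the 4 comparisons with control. ANKRD1, a cardiac ankyrin repeat protein and target of YAP signalling, rose 5.40-fold (log2 2.43 ± 0.20, adjusted p = 1.88e-06; 7.91 ± 0.53 SD against 5.48 ± 0.11 SD, n = 3). Heat shock genes rose with it: HSPA6 3.96-fold (1.98 ± 0.30, adjusted p = 0.00359), DNAJB1 2.98-fold (1.57 ± 0.22, adjusted p = 0.00153), HSPH1, an HSP110 chaperone, 2.17-fold (1.12 ± 0.15, adjusted p = 0.0015) and BAG3 1.48-fold (0.57 ± 0.11, adjusted p = 0.0489). The clusters shared by HSPA1A and HSPA1B rose by 0.68 to 0.94 (adjusted p = 0.00125 for each), and the one shared by HSPA7 and HSPA6 by 1.67 (adjusted p = 0.00239).

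Outside the chaperones in RHOXF2-transfected cells at 48 h, RFPL4A, a gene of the ret finger protein-like family, rose by 0.98 ± 0.12 (adjusted p = 0.000461), and its other cluster by 0.92 (adjusted p = 0.00125). PGBD5, a domesticated transposase gene, rose by 0.70 ± 0.11 (adjusted p = 0.00593) and the keratin-associated protein gene KRTAP19-5 by 0.62 ± 0.11 (adjusted p = 0.0291). ADAM20P1 fell by 0.94 (SE 0.14, adjusted p = 0.00359; 4.28 ± 0.19 SD against 5.22 ± 0.32 SD), and PRRT2, a synaptic membrane protein gene, fell by 0.58 (SE 0.09, adjusted p = 0.00593). Like ADAM20P1, PRRT2 had risen in control arrays between 24 h and 48 h, by 0.68. Next to the threshold were SNORA38 (-0.84, adjusted p = 0.0678), SNORD117 (-0.78, adjusted p = 0.0678) and the GABA receptor gene GABBR1 (-0.66, adjusted p = 0.092). In all, limma called 20 clusters with 14 names, 18 higher and 2 lower, and 2578 had an unadjusted p under 0.05. The 20 include RHOXF1, the RHOXF2 pair and several clusters of HSPA1A/HSPA1B.

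**Figure D3:**
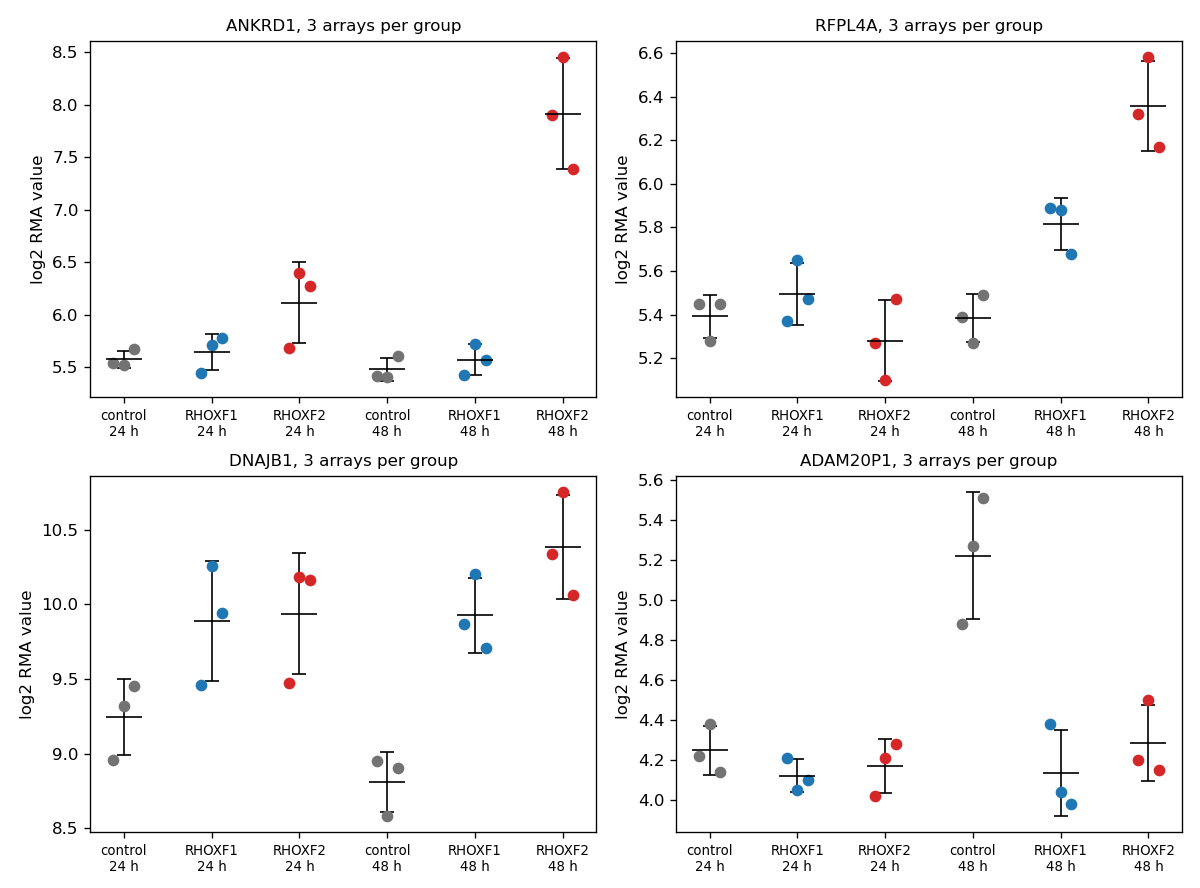
Log2 RMA level (y axis) of ANKRD1, RFPL4A, DNAJB1 and ADAM20P1 in the 6 groups (x axis); points are arrays and bars are the mean ± SD of 3. ANKRD1 stands at 7.91 in the RHOXF2 arrays at 48 h against 5.48 in control, while for ADAM20P1 the control arrays at 48 h, at 5.22, stand above the other groups.

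As a group, all 17 heat shock genes measured were higher in RHOXF2-transfected cells at 48 h (median 0.568, adjusted p = 3.55e-20; adjusted p = 0.0177 with an estimated correlation). This is the only list in the 4 comparisons with control whose call held with an estimated correlation. Of its members 5 were called over all genes and 14 when adjusted over the list alone; HSPB8 read 0.70 (adjusted p = 0.0602) and HSPA2 0.59 (adjusted p = 0.124). Between the control groups the same list moved down with time: its mean was 0.24 lower at 48 h, and the RHOXF2 arrays at 48 h stood 0.63 above the control arrays of their own time and 0.39 above those of 24 h. HSPH1, for one, averaged 10.48 in RHOXF2 arrays at 48 h, 9.36 in control at 48 h and 10.58 in control at 24 h. Small noncoding RNAs had 180 of 217 members lower (median -0.208, adjusted p = 4.66e-13; adjusted p = 0.822 with an estimated correlation), 6 of them called over the list alone. G1/S genes had 18 of 24 higher (median 0.109, adjusted p = 0.0138; adjusted p = 0.831 with an estimated correlation); CLSPN, a checkpoint adaptor, read 0.49 (0.21 in its other cluster) and CCNE2, a G1/S cyclin, 0.35. Replication-dependent histones had 16 of 19 higher (median 0.201, adjusted p = 0.0181; adjusted p = 0.831 with an estimated correlation), with H2AC4 at 0.65. The G1/S call was lost without control replicate 1 (adjusted p = 0.106), and that of histones without control replicate 2 (0.0882) or 3 (0.553) or RHOXF2 replicate 3 (0.176); the histone median was 0.356 without control replicate 1, and that of small noncoding RNAs -0.332 without RHOXF2 replicate 2. With repeated quantile normalization G1/S genes (median 0.10, adjusted p = 0.141; 0.00185 to 0.831 over the alternatives) and histones (0.192, adjusted p = 0.0676; 0.00578 to 0.831) were also lost.

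Single arrays moved the count at 48 h with RHOXF2: it was 125 without control replicate 1, 54 without RHOXF2 replicate 1, and 15 without RHOXF2 replicate 3, the array that stands apart on the first component. ANKRD1, HSPA6, DNAJB1, HSPH1 and RFPL4A were called in 6 of 6 such fits. BAG3 was lost without control replicate 2 (adjusted p = 0.207) or 3 (0.165) or RHOXF2 replicate 2 (0.115) or 3 (0.433), and KRTAP19-5 without control replicate 2 (0.183) or RHOXF2 replicate 2 (0.0973) or 3 (0.0968). Without control replicate 2 or RHOXF2 replicate 3, PGBD5 (0.0706 and 0.0688) and PRRT2 (0.0737 and 0.0633) were lost. The replicate block ended the calls of BAG3 (adjusted p = 0.0617; 0.0253 to 0.648 over the alternatives) and KRTAP19-5 (0.0634; 0.0119 to 0.497). These 2 were lost with all clusters as well (0.13 and 0.0883), BAG3 with array weights (0.086), and HSPA6 with trend and robust variances (0.0564; 0.0015 to 0.261). With only the 6 RHOXF2 and control arrays of 48 h fitted, 4 clusters were called: the RHOXF2 pair, ANKRD1 (adjusted p = 0.00618) and DNAJB1 (0.0238). HSPH1 then had 0.0533, the RFPL4A clusters 0.0533 and 0.178, and HSPA6, PGBD5 and ADAM20P1 0.261. PRRT2 had 0.462, KRTAP19-5 0.497, BAG3 0.648, and the HSPA1A/HSPA1B and HSPA7/HSPA6 clusters 0.162 to 0.178. Over the planned and added alternatives together the adjusted p of ANKRD1 ran from 1.36e-06 to 0.00618.

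**Figure D4:**
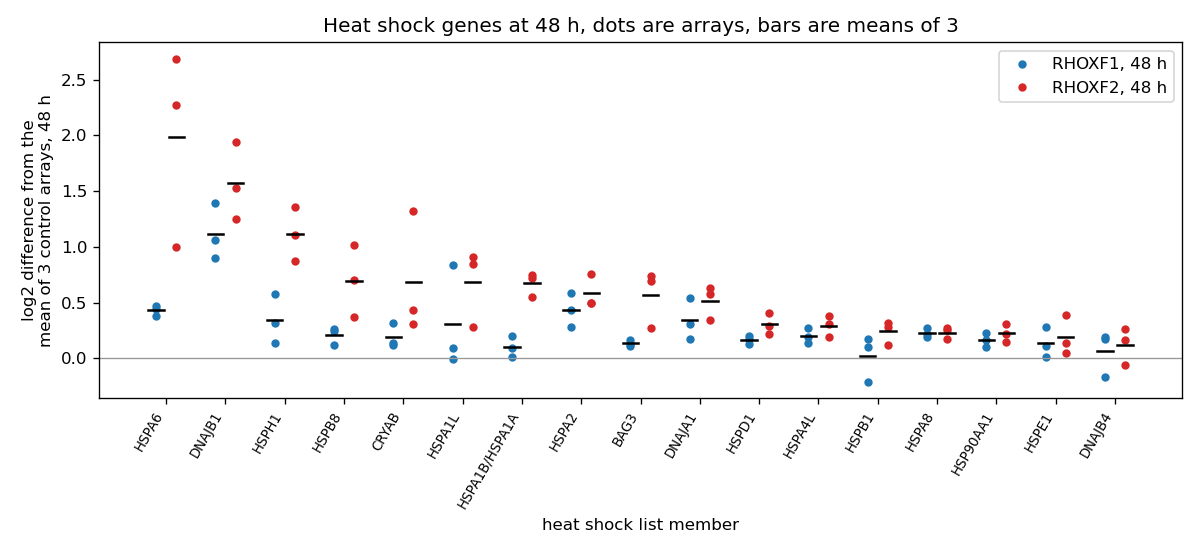
Log2 difference from the mean of the 48 h control arrays (y axis) for each of the 17 heat shock genes measured (x axis), with points for the RHOXF1 and RHOXF2 arrays at 48 h and bars for the mean of 3. The list median is 0.568 for RHOXF2 and 0.200 for RHOXF1.

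The remaining lists were not called in any comparison with control. Interferon-stimulated genes had medians of -0.032 and -0.023 at 24 h (RHOXF1 and RHOXF2; adjusted p = 0.972 for each) and of 0.037 and 0.033 at 48 h (adjusted p = 0.996 and 0.556). In RHOXF2 arrays at 48 h the medians were 0.043 for ER chaperones (adjusted p = 0.483), 0.085 for NF-kappa-B targets (adjusted p = 0.286), 0.109 for p53 targets (adjusted p = 0.134), -0.020 for apoptosis regulators (adjusted p = 0.402), 0.148 for oxidative stress genes (adjusted p = 0.0818) and -0.059 for hypoxia and glycolysis (adjusted p = 0.215). They were 0.021 for cholesterol synthesis (adjusted p = 0.47), 0.001 for G2/M genes (adjusted p = 0.782), -0.012 for HOX genes (adjusted p = 0.289), 0.051 for Sertoli and Leydig cell genes (adjusted p = 0.485), 0.039 for neuronal genes (adjusted p = 0.483) and -0.033 for ribosomal protein genes (adjusted p = 0.0889). Of their members, the intermediate filament gene INA read 0.79 ± 0.19 (adjusted p = 0.148 over all genes), and was called over its list alone. HOXD10 read -0.46 ± 0.11 (adjusted p = 0.154). Germ cell genes and markers of other cell types, called at 24 h, had medians of 0.016 (adjusted p = 0.782) and 0.033 (adjusted p = 0.905) in these arrays. The sign of the median changed under repeated quantile normalization or cyclic loess for interferon-stimulated genes at 24 h and for apoptosis regulators, G2/M genes and HOX genes with RHOXF2 at 48 h. It also changed at 24 h for ribosomal protein genes with either factor, and for HOX genes with RHOXF2. With RHOXF1 it changed for NF-kappa-B targets and apoptosis regulators at 24 h and for ER chaperones at 48 h.

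RHOXF1 and RHOXF2 were also compared with each other. At 48 h ANKRD1 was lower by 2.34 in RHOXF1 than in RHOXF2 arrays (log2 change -2.34 ± 0.20, adjusted p = 2.71e-06; 5.57 ± 0.14 SD against 7.91 ± 0.53 SD). GCM1, a placental transcription factor, was lower (-0.87 ± 0.12, adjusted p = 0.00467; 5.55 against 6.42), as were KRTAP19-5 (-0.70 ± 0.11, adjusted p = 0.0114) and the HSPA1A/HSPA1B clusters (-0.58 to -0.79, adjusted p = 0.0114 for each). Against control at 48 h, GCM1 read 0.57 with RHOXF2 (adjusted p = 0.0959) and -0.30 with RHOXF1 (adjusted p = 0.654). HSPA6 (-1.55 ± 0.30, adjusted p = 0.0937) and HSPH1 (-0.77 ± 0.15, adjusted p = 0.135) did not pass. All 17 heat shock genes were lower in RHOXF1 arrays (median -0.223, adjusted p = 1.15e-12; adjusted p = 0.11 with an estimated correlation). Of 11 clusters called, 1 was higher, RHOXF1 itself, and 10 were lower, the RHOXF2 pair among them. The count was 4 without RHOXF2 replicate 2 and 5 without RHOXF1 replicate 2 or 3. The GCM1 call was lost without RHOXF2 replicate 2 (adjusted p = 0.0554). KRTAP19-5 was lost without that array (0.148) or RHOXF1 replicate 1 (0.073), 2 (0.0654) or 3 (0.129), with the replicate block (0.0635) and with all clusters (0.0543; 0.00221 to 0.0635 over the alternatives). Calls were lost for the HSPA1A/HSPA1B clusters with all clusters (0.0521 to 0.0568), with only the groups compared (0.103 to 0.168; from 0.00215 over the alternatives) and without RHOXF2 replicate 2 (0.148) or RHOXF1 replicate 2 (0.119) or 3 (0.0865 to 0.0889), with a pair of them also lost without RHOXF2 replicate 1 (0.0685). At 24 h 3 clusters were called, and these were RHOXF1 and the RHOXF2 pair; DRC5 (0.46 ± 0.10) and the pregnancy glycoprotein gene PSG3 (-0.52 ± 0.11) came next (adjusted p = 0.521). Without RHOXF1 replicate 1 the count at 24 h was 5. By limma, 361 genes at 24 h and 747 at 48 h had an unadjusted p under 0.05, where 1061 are expected by chance.

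The genes called for both factors were few. At 48 h RHOXF1 was called higher and ADAM20P1 lower in both comparisons. These share their 3 control arrays, in which ADAM20P1 was high at 48 h (5.22 against 4.25 at 24 h). RHOXF1 is itself the transfected gene in the RHOXF1 arrays. Simulated unchanged groups with shared controls had 0 shared calls. They hold no changed gene and not the high ADAM20P1 control level, so that 0 cannot judge this overlap. The shared count at 48 h was 0 without RHOXF1 replicate 2 or 3, and 1 without RHOXF1 replicate 1, RHOXF2 replicate 3 or any control array. At 24 h the shared count was 0 by limma, and 484 genes had an unadjusted p under 0.05 for both with the same sign, against 219.5 in the simulations. At 48 h the latter count was 725 against 219.1. The simulations treat arrays as independent, while same-number arrays had residuals correlated at 0.06 to 0.52 at 24 h and at -0.35 to 0.24 at 48 h. Across genes, without the transfected ones, the effects of RHOXF1 and RHOXF2 correlated at 0.73 at 24 h and 0.71 at 48 h, where simulated unchanged groups against the same controls gave 0.50; genes are not independent replicates. The covariance exceeded the simulated one by 0.00456 and 0.0092. With separate controls, 1 array for one factor and the other 2 for the other, the correlation averaged 0.11 at 24 h (-0.07 to 0.29 over 6 divisions) and 0.18 at 48 h (-0.07 to 0.31), and the covariance 0.00268 and 0.00586. With single arrays that share neither control nor replicate number the correlation averaged 0.17 at 24 h (0.04 to 0.29) and 0.01 at 48 h (-0.17 to 0.38). Between 24 h and 48 h, which share no arrays, the correlation across genes was 0.14 for RHOXF1 and 0.10 for RHOXF2, and the shared calls were the transfected genes alone.

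The effect of RHOXF2 differed between the times for ANKRD1, whose rise was 1.89 ± 0.28 larger at 48 h (adjusted p = 0.0168; 0.54 above control at 24 h), and for RFPL4A, in both clusters (1.09 ± 0.16, adjusted p = 0.0168, and 1.28 ± 0.17, adjusted p = 0.00914). Both genes belong to no list. The count of 3 became 0 without control replicate 3 of 24 h, and 1 without RHOXF2 replicate 1 or control replicate 1 of either time or control replicate 2 of 48 h. In each of these 6 fits ANKRD1 was lost (adjusted p from 0.0593 to 0.0915), as it was without control replicate 2 of 24 h (0.0504). The first RFPL4A cluster was lost in the same 6 fits (0.0593 to 0.0915), and without RHOXF2 replicate 2 of 24 h (0.085) or 48 h (0.06), and the other without control replicate 3 of 24 h (0.0513). With cyclic loess the count was also 0 (adjusted p = 0.0619 for ANKRD1, 0.127 and 0.0598 for RFPL4A); the first RFPL4A cluster was also lost with the replicate block (0.0622), and over the alternatives ANKRD1 ran from 0.0106 to 0.13 and RFPL4A from 0.00636 to 0.13. For RHOXF1, limma called 0 genes for a difference between times, with 998 at an unadjusted p under 0.05; without RHOXF1 replicate 1 of 48 h the count was 1. ADAM20P1 (-0.95), CLDN1 (0.66) and CCDC88C (0.58; 0.05 in its other cluster) were among those with the smallest p (adjusted p = 0.95).

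Control cells at 48 h were also compared with control cells at 24 h, where more genes were called than in any comparison of transfected with control cells. ZC3H6, a zinc finger gene, was 3.63-fold higher at 48 h than at 24 h (1.86 ± 0.32, adjusted p = 0.00133), and ABI3BP (1.61 ± 0.24), FAXDC2 (1.51 ± 0.25), the small GTPase gene RRAS (1.42 ± 0.19) and the neural adhesion gene L1CAM (1.37 ± 0.24) rose too. HSPH1 fell by 1.22 (SE 0.15, adjusted p = 0.000344), the histone gene H2AC4 by 1.14, NOL6, a nucleolar protein gene, by 1.14, the fatty acid transport gene SLC27A4 by 1.11 and PIGW by 1.09. The replicate block compares the times at the reference replicate of each and not at the group means. Under it H2AC4 (-0.95, adjusted p = 0.0717) and PIGW (-0.88, adjusted p = 0.0548) were not called, which does not bear on their mean change. Over the alternatives their adjusted p ran from 0.00126 to 0.0717 and from 0.00151 to 0.0548. ATF4 targets had 16 of 20 members higher (median 0.404, adjusted p = 0.00252; adjusted p = 0.538 with an estimated correlation), and hypoxia and glycolysis genes 18 of 21 (median 0.288, adjusted p = 0.0104; adjusted p = 0.666 with an estimated correlation). Oxidative stress genes had 17 of 17 lower (median -0.187, adjusted p = 0.00993; adjusted p = 0.538 with an estimated correlation), histones 13 of 19 lower (median -0.361, adjusted p = 0.0287; adjusted p = 0.621 with an estimated correlation) and heat shock genes 13 of 17 lower (median -0.247, adjusted p = 0.0107; adjusted p = 0.538 with an estimated correlation), although HSPB1 rose by 0.61. In all 3772 genes were called, 2098 higher and 1674 lower; with arrays centred on their medians, which shifts the median of all genes by -0.071, the directions became 1519 higher and 3659 lower. With only the control arrays fitted 1595 were called. The replicate block gave 984, again at the reference replicates only, so that count cannot be set against 3772. The count was 2125 without control replicate 2 of 24 h, and 2396 and 2073 without control replicates 2 and 3 of 48 h. Time and array batch cannot be told apart here.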

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

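The tests of the time course against control at 24 h, of single arrays, of a response common to both transfected genes, of binding between transcripts and of an offset by level were chosen only after the result was seen.

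Heat shock genes stood higher in RHOXF2 than in control arrays at 48 h (median 0.568). If control arrays were merely further along the change from 24 h to 48 h, the RHOXF2 arrays at 48 h would lie between the control groups of both times; their list mean lay 0.39 (SE 0.08) above control at 24 h, which argues against this as the whole cause, unless an offset between the array batches adds to it. Removing each array's deviation along the change in the RHOXF1 groups decides nothing for this list, whose mean moved there by only -0.08: its median stayed at 0.517, and the same removal took histones from 0.201 to 0.129 (p = 0.0566 with the preset and 0.445 with an estimated correlation), small noncoding RNAs from -0.208 to -0.136 (2.64e-13 and 0.0858) and G1/S genes from 0.109 to 0.105 (0.00501 and 0.213). A single RHOXF2 array is argued against, since the lowest median without any of these was 0.484. An equal response to either transfected gene is left open. The list mean was 0.36 (SE 0.08) higher with RHOXF2 than with RHOXF1 (camera p = 0.00131 with an estimated correlation). Adjusted over lists that p was 0.11, and the list was singled out for its rise in these same RHOXF2 arrays. An effect of RHOXF2 itself, one growing with the amount of any introduced protein, or an equal response to either gene may underlie the rise. The amounts were not measured. No group is labelled as transfected with an unrelated protein, and whether the RHOX plasmids encode GFP is not stated.

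RHOXF1 read 1.84 above control in RHOXF2 arrays at 48 h. RHOXF2 transcript binding to the RHOXF1 probes could give this, and the RHOXF1 level ranged over 2.18 across the 6 RHOXF2 arrays while the RHOXF2 cluster ranged over 0.18. That test decides nothing, because the RHOXF2 cluster lies at or above percentile 99.1 of its arrays, where signal can be compressed; this limit was set with the level in view. A single array is open as well: the lowest rise without 1 RHOXF2 array was 1.26, above 0.5 of the full rise but no longer past the threshold (adjusted p = 0.0998; 0.00371 to 0.148 over the arrays left out). Binding between the transcripts, a few arrays, and a rise of RHOXF1 itself cannot be told apart here.

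Germ cell genes and markers of other cell types read lower in transfected arrays at 24 h. Many of these genes are dim, and dim genes in general read lower at that time. Against random lists of the same levels, the medians lay at percentile 32.1 (germ cell genes, RHOXF1), 15.9 (germ cell genes, RHOXF2) and 12.1 (other cell types, RHOXF2), all inside the central range, which is consistent with an offset between arrays that depends on level. Immediate early (83.4) and heat shock genes (97.1) with RHOXF1 and G1/S genes (96.3) with RHOXF2, which read higher at 24 h, lay inside it too. Heat shock genes, ATF4 targets and histones with RHOXF2 lay above it (100 each). Random lists draw genes singly and leave out the correlation among members, so these percentiles do not measure chance. With an estimated correlation the camera adjusted p was 0.361 for these heat shock genes and 0.831 for ATF4 targets and for histones. A change in germ cell genes or markers of other cell types beyond an offset by level was not seen, and no biological explanation was tested.

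The effect of RHOXF2 differed between 48 h and 24 h for ANKRD1 (1.89) and for the RFPL4A clusters (1.09 and 1.28), by a test of the difference itself. Lists that differed between the times with the preset correlation were heat shock genes (median 0.221, adjusted p = 2.03e-05; adjusted p = 0.767 with an estimated correlation), ATF4 targets (-0.224, adjusted p = 0.0257; adjusted p = 0.89 with an estimated correlation), ribosomal protein genes (-0.043, adjusted p = 0.032; adjusted p = 0.89 with an estimated correlation) and small noncoding RNAs (-0.226, adjusted p = 2.21e-10; adjusted p = 0.89 with an estimated correlation) for RHOXF2. The median of ribosomal protein genes was 0 after repeated quantile normalization. For RHOXF1, G2/M genes differed (-0.09, adjusted p = 0.0174; adjusted p = 0.89 with an estimated correlation).

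Clusters without a gene symbol were not used in the comparisons of the report. Among 12083 of them, tested together with the named ones, 1 was called for RHOXF2 at 24 h (-0.63), 1 for RHOXF1 at 48 h (-0.52) and 3 for RHOXF2 at 48 h (largest fall -1.12), all lower than control.

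With 10 splits of 6 arrays a share under 0.05 cannot be reached, so real values are given beside the highest of the other splits. The splits treat arrays as independent, although residuals of same-number arrays at 24 h correlated above 0.1 in 8 of 9 pairs. For genes at 24 h, RHOXF1 gave 1 call against 0 and RHOXF2 2 against 0, so that 1 split of 10 was as large in each case. These calls, and the 3 of RHOXF1 against RHOXF2 at 24 h, are the transfected genes themselves. Any mixed split breaks up their rise, so these outcomes tell nothing about other genes. At 48 h RHOXF1 gave 2 against 0 (1 split of 10) and RHOXF2 20 against 68 (2 splits of 10). Of the 2 calls for RHOXF1, 1 is RHOXF1 itself, whose rise any mixed split breaks up, so that outcome was partly fixed in advance. RHOXF1 against RHOXF2 gave 3 against 0 at 24 h (1 split) and 11 against 30 at 48 h (2 splits), and control arrays over time 3772 against 2 (1 split). For lists, the real and highest other counts were 4 and 6 (RHOXF1 at 24 h, 6 splits of 10 as large), 6 and 6 (RHOXF2 at 24 h, 2 splits), 2 and 8 (RHOXF1 at 48 h, 10 splits) and 4 and 7 (RHOXF2 at 48 h, 9 splits). For the differences between times, 6 of 100 splits gave as many calls as the 3 of RHOXF2 (highest other 444), so chance cannot be excluded. For RHOXF1 the real count of 0 decides nothing, since all 100 of 100 splits reach it (highest other 2). The splits with 68 and 30 calls point to a structure among the arrays at 48 h other than their groups. That with 68 puts RHOXF2 replicate 1 with control replicates 2 and 3. Splits for the differences between times regroup the 24 h arrays as well, so the 444 calls cannot be assigned to 48 h.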

How the results depend on the processing

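Cyclic loess was chosen after seeing the data; the other alternatives were planned. The median of germ cell genes with RHOXF1 at 24 h reversed, from -0.044 to 0.018, with clusters above the median level. Each result was counted once per setting, so the shares below are not shares of separate findings. The rises of the transfected genes in their own arrays are among them. Kept means the same direction and side of the threshold, or a count within 1.5 times. Apart from the fits that leave out an array, 201 of 242 pairs of main result and setting were kept. For single genes and lists 436 of 534 pairs were kept, and 97 of the 534 fell short of the threshold. With arrays left out singly, 142 of 180 and 267 of 348 pairs were kept. The cause was not tested for the changes below. Fits of only the groups compared use fewer arrays and the spread of those groups alone. The main fit used 1 spread per cluster for all groups. The mean SD of a cluster was 0.144 in control, 0.133 in RHOXF2 and 0.103 in RHOXF1 arrays at 48 h. In the 24 h groups it ran from 0.111 to 0.137. How far signal lay over background is not in the table, so its limit on dim genes is unknown.

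With only the groups compared, calls were 1 (RHOXF1, 48 h), 4 (RHOXF2, 48 h), 6 (RHOXF1 against RHOXF2, 48 h), 0 (RHOXF2 difference between times) and 1595 (control over time). With clusters above the median level they were 1, 13 and 0 for RHOXF1 at 48 h, RHOXF2 at 48 h and the RHOXF2 difference. With a replicate block they were 5 (RHOXF1, 48 h). For control over time the block gave 984, but it compares the times at the reference replicate of each, so that count is no alternative for the mean change. With an unadjusted threshold and a 2-fold change they were 4 (RHOXF1, 48 h), 11 (RHOXF2, 48 h), 5 (RHOXF1 against RHOXF2, 48 h), 8 (RHOXF2 difference) and 62 (control over time). With all clusters, named or not, RHOXF1 against RHOXF2 at 48 h had 5 and the RHOXF2 difference 0; with cyclic loess the latter had 0.

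RHOXF1 in RHOXF2 arrays at 48 h (1.84) missed the threshold with only the groups compared (1.84, adjusted p = 0.648), trend and robust variances (1.84, adjusted p = 0.164), clusters above the median level (1.84, adjusted p = 0.051), all clusters (1.84, adjusted p = 0.166) and array weights (1.52, adjusted p = 0.141). Genes called for both factors at 48 h were 0 with only the groups compared and with clusters above the median level, 1 with trend and robust variances, array weights and all clusters, and 5 with the block; at 24 h there was 1 with the 2-fold threshold. Lists called for RHOXF1 at 24 h (4) were 1 above the median level, 2 with cyclic loess and 0 with an estimated correlation. For RHOXF2 at 24 h (6) they were 3 above the median level and with repeated quantile normalization, 2 with cyclic loess and 0 with an estimated correlation. For RHOXF1 at 48 h (2) they were 5 with array weights and 0 with an estimated correlation, and for RHOXF2 at 48 h (4) 2 with repeated quantile normalization and 1 with an estimated correlation.

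Leaving out 1 array at a time gave these ranges of calls: RHOXF1 at 24 h 1 to 1 and at 48 h 1 to 4, RHOXF2 at 24 h 2 to 7 and at 48 h 15 to 125, RHOXF1 against RHOXF2 3 to 5 and 4 to 12, differences between times 0 to 1 (RHOXF1) and 0 to 3 (RHOXF2), control over time 2073 to 4077, and genes shared by both factors 0 to 2 at 48 h. RHOXF1 in RHOXF2 arrays at 48 h ranged from 1.26 to 2.31. Lists called ranged from 1 to 6 and 3 to 7 at 24 h and from 2 to 5 and 4 to 6 at 48 h (RHOXF1, then RHOXF2). RHOXF1 in its own arrays ranged from 5.81 to 6.02 at 24 h and 5.92 to 6.34 at 48 h, and RHOXF2 in its own from 5.88 to 6.17 and 6.21 to 6.46. In RHOXF1 arrays RHOXF2 ranged from -0.59 to -0.09 and from -0.45 to -0.01, and RHOXF1 in RHOXF2 arrays at 24 h from 0.94 to 1.41.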

Other observations

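For the placental transcription factor GCM1, control arrays stood between the transfected groups at 48 h, with a level of 5.55 in RHOXF1, 5.85 in control and 6.42 in RHOXF2 arrays. PRRT2 was lower in both transfected groups, at 7.74 with RHOXF1 and 7.51 with RHOXF2, against 8.08 in control at 48 h; the difference with RHOXF1 did not pass (adjusted p = 0.484). PGBD5 read 0.30 above control with RHOXF1 at 48 h (adjusted p = 0.594) and RFPL4A 0.44 (adjusted p = 0.482), beside the rises of 0.70 and 0.98 with RHOXF2.

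For RHOXF1 against RHOXF2, the lists with a preset-correlation call besides heat shock genes at 48 h were ribosomal protein genes (median 0.060, higher with RHOXF1, adjusted p = 0.000324; adjusted p = 0.89 with an estimated correlation) and small noncoding RNAs (0.090, 154 of 217 higher, adjusted p = 8.13e-05; adjusted p = 0.89 with an estimated correlation). At 24 h they were heat shock genes (-0.075, adjusted p = 0.000519; adjusted p = 0.767 with an estimated correlation), small noncoding RNAs (-0.083, 161 of 217 lower and so opposite to 48 h, adjusted p = 7.18e-08; adjusted p = 0.89 with an estimated correlation), immediate early genes (0.054, adjusted p = 0.0111; adjusted p = 0.89 with an estimated correlation) and ATF4 targets (-0.105, adjusted p = 0.032; adjusted p = 0.89 with an estimated correlation).

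In control cells between the times, 4 lists had smaller shifts. Ribosomal protein genes had a median of 0.099 (adjusted p = 0.00252, or 0.538 with an estimated correlation) and HOX genes 0.087 (adjusted p = 0.0417, or 0.538). Immediate early genes had 0.159 (adjusted p = 0.0309, or 0.621) and small noncoding RNAs 0.104 (adjusted p = 0.0274, or 0.718). Centring arrays on their medians shifts the median of all genes here by -0.071, so the size of these medians depends on the scaling.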
